A study of Mus musculus with 24 samples.

How the data were processed

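Messenger RNA from single mouse cells was measured on 24 microarrays in 7 groups. The groups were metaphase II (MII) oocytes, taken as 0 h, and 1-cell embryos made by intracytoplasmic sperm injection (ICSI) and collected 2, 4, 6, 8, 10 and 12 h later, with 3, 3, 4, 3, 3, 4 and 4 cells in that order. Groups and replicate letters were taken from the sample titles. Per the labels' protocols, mRNA of each cell was captured on oligo-dT beads, copied with random and oligo-dT primers, tailed with poly-G and amplified by PCR with a single primer, so that every value passed through a whole-transcriptome amplification of 1 cell. The labels' protocols speak of a digoxigenin-labelled sample and a biotin-labelled reference, while the label field reads biotin; which of these the deposited values come from is not given in the sources used here, and 1 value per probe and array was analysed.

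The deposited values are scores, not log2 values. The submitters' processing notes name limma, without a version; background correction, scanner and other steps are not given in the sources used here. The 24 deposited columns had near-identical distributions, with medians between 1.16 and 1.18, as quantile normalization between arrays leaves them. The scores ran from 0 to 4.57 with a standard deviation of 1.00. Their scale was read from tied probes: quantile normalization places a tied probe midway between neighbouring levels on the scale that was normalized, and 767 such midpoints followed the curvature of a natural log of a natural log of intensity, divided by 0.225, with the lowest intensity at 0. The largest residual of the curvature was 0.0200, against fitted values of 1.11 to 2.68. Turned back, the values spanned intensities of 51.2 to 58904, below the ceiling of 65536 of an integer scanner scale. On simulated arrays of 40000 probes the same steps recovered log2 intensity with a largest error of 0.0171. The method fixes intensity only up to a shift and a factor, so the log2 intensities, 5.68 to 15.85, rest on the scanner-like range and step size, and no background was subtracted. The most common log2 intensity was 6.78, which is taken as the background level; changes of genes near it are understated. Saturated spots could not be told from others. The planned test asked for log2 of values that were not log2, so the tests were run on the recovered log2 intensity, and the deposited scores were tested as they are in an alternative that was chosen after seeing the data.

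The platform annotation gave 1 gene symbol for 32664 of the 41174 probes, several for 45 and none for 8465. Symbols were checked through Entrez identifiers against the NCBI RefSeq gene table of the GRCm38.p6 assembly, which matched 32524 probes and changed 0 symbols. The build of the probe design is not given in the sources used here, so no coordinates are printed. The probe with the highest mean over the 24 arrays stood for a gene, which gave 19532 genes, 8511 of them with more than 1 probe. For 88 pairs of a named gene and a comparison with more than 1 probe, another probe over 1 log2 unit above background moved the other way in 10, covering 9 genes: Marchf7, Cct2, Hspa8, Hspa1b, Pim1, Suv39h2, Ubtf, Eif5 and Dhx16. The sizes of change given are those of the 1 probe used, and other bright probes of some genes moved the same way by less or by more. No 2 arrays were copies of each other, the smallest mean absolute difference between 2 arrays being 0.51 log2 units.

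All 24 arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes with trend) of 7 group means, so that all groups shared 1 estimate of the spread. Each time was compared with 0 h and with the time before it, which makes 11 two-sided comparisons. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, with no minimum change. A moderated F-test covered all 7 times, and a linear slope per hour was fitted to the 21 embryos without the oocytes. The 22 gene lists were tested with camera at a preset correlation of 0.01 in each of the 11 comparisons, with adjustment over all 242 tests. The lists covered oocyte maternal genes, mRNA decay, 2-cell-stage genes, immediate early genes, chaperones, ribosomal proteins, ribosome biogenesis, general transcription, splicing, proteasome, translation factors, DNA replication, mitosis, oxidative phosphorylation, chromatin, pluripotency, p53 targets, unfolded protein response, sterol synthesis, and markers of sperm, cumulus and blood cells. The series' design text calls the arrays biological replicates; no label ties cells to animals, so p-values measure the spread between these cells. In simulated data with 19532 genes and 200 changed genes, 12 h against 0 h recovered 10.6% of changes of 1 log2 unit, 56.7% of 2 and 89.6% of 4, with 8 false calls. For 2 h against 0 h the shares were 15.2%, 46.3% and 83.6%, with 7 false calls. A simulated list of 50 genes, all shifted by 1 log2 unit, was found, and 0 of 20 unshifted lists had a camera p under 0.05. Genes were simulated as independent, with 1 SD per gene in all groups and 1 simulation per comparison. These shares and this list test therefore may not hold for the real groups and lists.

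Groups, tests, lists and most alternatives were fixed before the data were examined. Named genes followed a fixed rule: the 10 higher and 10 lower genes with the largest change at 12 h against 0 h, 6 and 6 at the other times, 3 and 3 for consecutive times and for the slope, among changed genes whose groups did not overlap (no such condition for the slope), up to 4 members of each list by smallest p, and a fixed set of genes named beforehand. Of that set, Ccnb1 and Zscan4d were not analysed here. The alternatives were no mean-variance trend, the upper 60% of genes by mean level, median centring, quantile normalization again, the mean of all probes of a gene, array weights, a replicate block, robust eBayes, only the groups compared in the fit, a minimum change of 1 log2 unit, and each of the 24 arrays left out. For lists they were camera with an estimated correlation, fry and a replicate block. The dimness of an array was taken from the spacing of its tied intensities, which was 0.50 to 0.56 units in the oocytes and up to 2.33 in embryos over a fixed low range of intensities. Leaving out the 4 arrays with a spacing over 2 units was added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the scale and the plots.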

Results

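The abundance of mRNA captured on oligo-dT beads was measured in single MII oocytes and in single 1-cell mouse embryos at 2 h intervals after ICSI. MII oocytes are arrested in the second meiotic division before fertilization, and in ICSI a sperm is injected into the oocyte. Oocytes and sperm came from B6D2F1 mice, a hybrid strain. There were 3 oocytes at 0 h, 3 embryos at 2 h, 4 at 4 h, 3 at 6 h, 3 at 8 h, 4 at 10 h and 4 at 12 h, each on its own array, and this number limits the precision. Values are log2 intensities recovered from the deposited scores, with the background at about 6.78, and are given as mean ± SD over the cells of a group. The 3 oocytes resembled each other most, with pairwise Pearson correlations across genes of 0.93 to 0.94 and a median SD of a gene of 0.28, while embryos of 1 time correlated at 0.81 to 0.92 with median SDs of 0.46 to 0.54. The oocyte arrays also had the finest intensity steps, 0.53 units on average against 0.95 to 1.46 units in the embryo groups. Adjusted p-values are from limma.

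The comparison of 12 h embryos with oocytes spans the whole course, and the genes with the largest falls were bright in the oocytes. A large fall is possible only from well above background, so this brightness follows in part from the choice of genes. Mos, the kinase that holds the oocyte in metaphase, fell from 15.19 ± 0.15 (SD, n = 3) to 9.53 ± 1.69 (SD, n = 4), a log2 change of -5.66 (SE 0.77, adjusted p = 0.000685). Plat, tissue-type plasminogen activator, went from 15.51 ± 0.20 to 10.28 ± 1.74, a change of -5.23 (SE 0.78, adjusted p = 0.0012), while another bright probe of Plat changed by -2.63. Atf6b, a membrane-bound transcription factor of the endoplasmic reticulum, fell by 5.53 (SE 0.55, adjusted p = 1.29e-05), reaching 7.73 ± 0.34. Tm9sf3 and Tmed9, membrane proteins of the secretory pathway, had log2 changes of -5.71 and -5.09, Has3, a hyaluronan synthase, one of -5.08, and Smc3, a cohesin subunit, one of -5.28. Klhl18, Rnf215 and Marchf7, which are linked to ubiquitin ligases, had changes of -5.10, -5.24 and -5.94. Another probe above background changed by -0.90 for Tm9sf3, -3.11 for Smc3 and -3.70 for Klhl18, so the sizes given for these genes hold for 1 probe. Another bright probe of Marchf7 went up by 2.18, so its direction is unsettled. In all, 205 genes were lower and 80 higher than in the oocytes, of 19532 tested. Their median absolute change was 2.69, while the median over all genes moved by 0.08. The count of 285 was 104, 131 and 128 without 0 h replicates a, c and d, 162 with only these groups in the fit (139 lower, 23 higher) and 976 with array weights. The excess of lower genes was smaller in some settings, with 532 lower and 444 higher with array weights and 227 and 174 without the mean-variance trend.

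The 10 named genes that rose most by 12 h had mean levels of 6.60 to 10.84 in the oocytes, the highest being that of Txndc9. Slco1a5, an organic anion transporter, rose from 6.94 ± 0.23 to 12.05 ± 1.22, a log2 change of 5.11 (SE 0.97, adjusted p = 0.00742), and Slco1a1, of the same family, rose by 3.36 (SE 0.63). Gjd3, a connexin, rose from 8.74 ± 0.24 to 13.24 ± 1.02, and Arg2, the mitochondrial arginase, by 4.43 (SE 0.82, adjusted p = 0.00616). Pramel39 and Pramel37, members of a gene family of the germ line and early embryo, rose by 4.05 and 3.54, with wide spreads at 12 h of 2.30 and 2.25. Gm7969 rose by 4.25, the noncoding RNA Snhg5 by 3.96, the histone gene H4c14 by 3.50 and Txndc9 by 3.29. Other probes of Txndc9 rose by only 1.34 and 0.45, and the call of H4c14 was lost in 8 of 35 alternative settings. The median 0 h level was 8.80 for the 80 genes that rose and 12.38 for the 205 that fell, and 40 and 190 of them were more than 2 log2 units above background at 0 h. Background limits how far a dim gene can fall, and the 0 h values entered the choice of genes. This contrast is therefore partly built in.

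Among the lists fixed beforehand, the 2-cell-stage genes, known to be transcribed when the embryonic genome becomes active, had the smallest camera p of the lists at 12 h. Only 23 of the 43 genes fixed for this list were measured. Of these 23 members 4 rose, 0 fell and 19 did not pass, and 6 rose when adjusted over the list alone. Usp17lc, a deubiquitinating enzyme, rose by 3.15 (SE 0.56, adjusted p = 0.00509), Gm5662 by 2.93 (SE 0.54, adjusted p = 0.00597) and Zfp352, a zinc finger gene, from 7.22 ± 0.24 to 10.12 ± 1.78, a change of 2.90 (SE 0.71, adjusted p = 0.0413). Arg2 was the other member, and all 4 of these genes were higher in each of the 4 embryos of 12 h than in any oocyte. This was not confined to 12 h. Of all 21 embryos, 13, 12, 13 and 19 were above every oocyte for Zfp352, Usp17lc, Gm5662 and Arg2. Eif1a, another member, was at 8.09 ± 0.66 and 8.16 ± 0.30. The list itself did not pass after adjustment over the 242 tests (camera adjusted p = 0.0864; adjusted p = 0.267 with an estimated correlation), although fry, which does not compare a list with other genes, gave an adjusted p of 0.000428. The call of Zfp352 was lost in 12 of 35 alternative settings.

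Of the 37 measured oocyte maternal genes, 3 fell by 12 h, 0 rose and 34 did not pass, with the same 3 called when adjusted over the list alone. Gdf9, a growth factor secreted by the oocyte, fell from 15.28 ± 0.07 to 13.56 ± 0.39, a log2 change of -1.71 (SE 0.20, adjusted p = 0.000134). H1f8, the linker histone of the oocyte, fell from 14.13 ± 0.17 to 12.63 ± 0.73, and Zar1 fell by 1.05, calls lost in 3 and 9 of 35 alternative settings. Zp3, a protein of the zona pellucida, was at 11.96 ± 1.42 and 9.23 ± 1.07, and missed the threshold (adjusted p = 0.15). Btg4 was at 14.14 ± 0.14 and 14.11 ± 0.26, and Dppa3 at 14.04 ± 0.28 and 14.57 ± 0.21, neither past the threshold (adjusted p = 0.978 and 0.302). The list's median change was 0.01, its mean was -0.33, and its camera adjusted p was 0.254 (adjusted p = 0.354 with an estimated correlation).

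In the mitosis list, 2 of 64 measured genes fell and 0 rose at 12 h, and 4 fell and 1 rose when adjusted over the list alone. These were Mos and Bub1b, a spindle checkpoint kinase, which fell from 15.29 ± 0.19 to 10.47 ± 1.28. Cdk1, the mitotic kinase, was at 9.37 ± 0.59 and 12.39 ± 0.85, just outside the threshold (adjusted p = 0.0548). Of 50 mRNA decay genes 3 fell, namely Lsm5, Tob2 and Cnot11, with log2 changes of -4.38, -1.56 and -1.76, and 0 rose; adjusted over the list alone 4 fell. Of 32 genes of the unfolded protein response only Ern1, which encodes the stress sensor IRE1, passed, falling from 14.73 ± 0.14 to 11.83 ± 0.66 (log2 change -2.90, SE 0.36, adjusted p = 0.000251), and adjusted over the list alone 3 fell. Insig1, a sterol sensor, fell by 1.45 as the 1 called gene of 20 in the sterol list, where 3 fell and 1 rose when adjusted over the list alone. For these 4 lists the camera adjusted p was 0.267, 0.22, 0.22 and 0.683. The calls of Cnot11, Tob2 and Lsm5 were lost in 12, 8 and 6 of 35 alternative settings.

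The 71 measured ribosomal protein genes had a median change of 0.49 against 0 h, with 0 called over all genes and 8 higher, 0 lower when adjusted over the list alone; Rpl9, Rpl12, Rpl17 and Rps6 had changes of 2.70, 2.73, 1.65 and 2.16. The camera adjusted p was 0.0864, and adjusted p = 0.267 with an estimated correlation. Of 73 oxidative phosphorylation genes 1 rose, over all genes and when adjusted over the list alone: Atp5pb, an ATP synthase subunit, rose by 2.55 (SE 0.62, adjusted p = 0.0385), a call lost in 8 of 35 alternative settings. The list's median change was 0.28 (camera adjusted p = 0.543). Of 41 immediate early genes 1 rose by either count, Gadd45g, by 2.78 (SE 0.49, adjusted p = 0.00432), and Myc was at 8.35 ± 0.08 and 9.20 ± 0.58. No list passed in any of the 11 comparisons with camera at either correlation, while 34 of the 242 tests had an unadjusted p under 0.05 and 5 passed with fry.

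**Figure D1:**
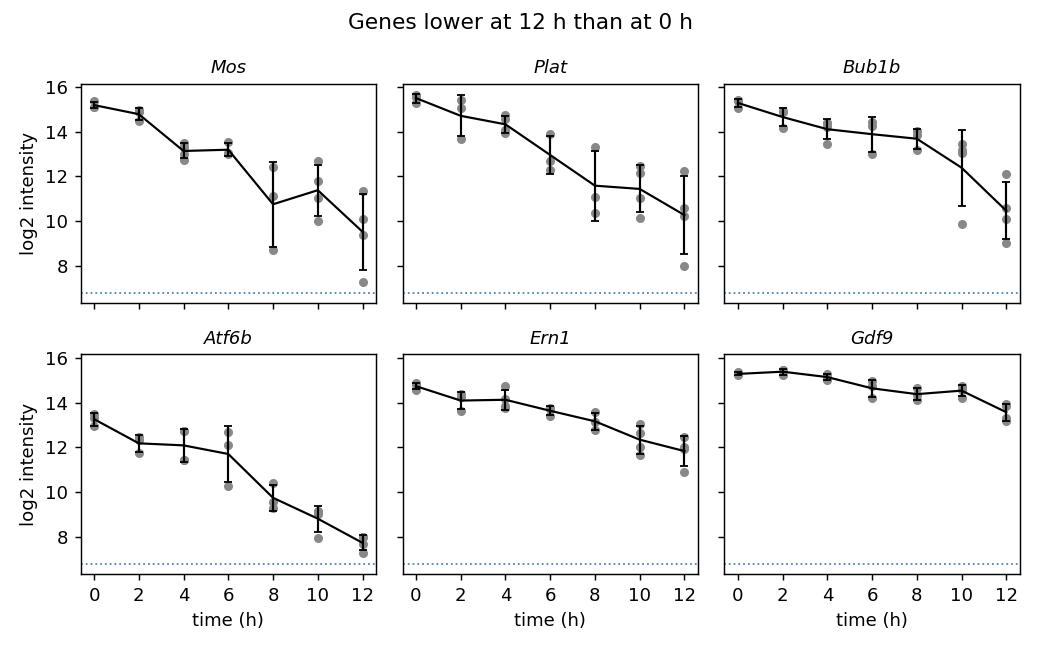
Log2 intensity (vertical axis) against hours after sperm injection (horizontal axis) of 6 genes lower at 12 h than at 0 h; grey points are single cells, black lines and bars the mean and SD, the dotted line the background. Mos falls from 15.19 to 9.53 and Gdf9 from 15.28 to 13.56.

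**Figure D2:**
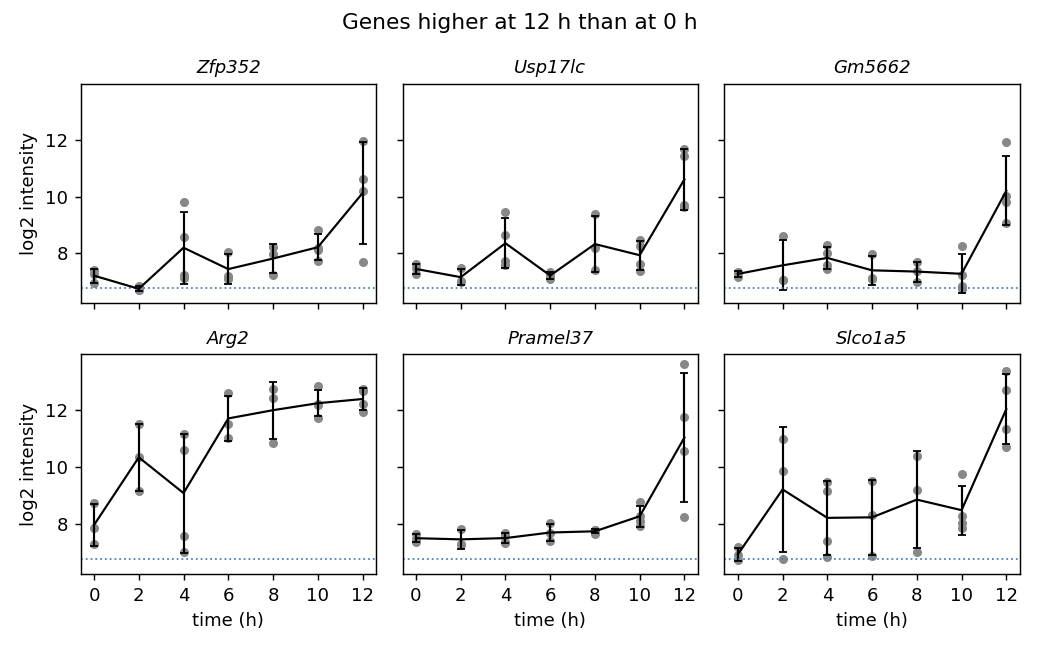
Log2 intensity (vertical axis) against hours after sperm injection (horizontal axis) of 6 genes higher at 12 h than at 0 h; grey points are single cells, black lines and bars the mean and SD, the dotted line the background. Gm5662 stays between 7.28 and 7.84 on average up to 10 h and is at 10.20 at 12 h, while Arg2 is already at 11.72 at 6 h.

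At 10 h, 113 genes were lower and 26 higher than in the oocytes, against 115 and 75 without the mean-variance trend and 475 and 427 with array weights. Tmed9 fell by 4.94 (SE 0.82, adjusted p = 0.00788), and C1qtnf12, the zinc transporter gene Slc39a9, Dcun1d2, Med11 and Dipk1b had log2 changes of -5.04, -4.90, -4.89, -5.07 and -4.80. Gjd3 and Arg2 rose by 4.57 and 4.28, Gpx4, a glutathione peroxidase, by 2.94, Olfr976 by 2.83, Mamld1 by 2.60 and Lbx1 by 2.48; the calls of Med11, Dipk1b and Lbx1 were lost in 21, 18 and 16 of 35 alternative settings. Of the lists, the mitosis genes Mos, Kif23 and Bub1b had log2 changes of -3.80, -1.54 and -2.90, and Lsm5 of the decay list, Ern1 and the translation factor Eif4h had -4.51, -2.39 and -3.11. Besides Arg2, the only list member that rose past the threshold over all genes was Prm1 of the sperm list, by 1.40 from 11.36, a probe already bright in the oocytes. Adjusted over the list alone, Gapdhs and Prm2 of the sperm list rose as well, by 1.62 and 2.82, as did the immediate early gene Gadd45g, by 1.96, and Gdf9 fell by 0.75; the other list members named here were called by both counts. The 139 calls became 41, 52 and 24 without 0 h replicates a, c and d, 67, 73 and 83 without 10 h replicates a, b and c, 85 without the 4 dim arrays (an alternative chosen after seeing the data; 66 shared) and 902 with array weights.

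At 8 h, 92 genes were lower and 83 higher. This majority turned in 6 settings. There were 95 higher and 89 lower without the mean-variance trend, and 326 and 268 with array weights. Without 8 h replicates a, c and d there were 107 and 78, 101 and 70, and 102 and 53. Without the 4 dim arrays (chosen after seeing the data) there were 73 and 50, with 67 of the 175 calls shared. Taldo1, transaldolase of the pentose phosphate pathway, fell from 13.29 ± 0.49 to 7.13 ± 0.29, a log2 change of -6.16 (SE 1.01, adjusted p = 0.0125). Vwa2, Marchf7, Tpra1, Slc39a9 and C1qtnf12 had changes of -5.77, -5.74, -5.60, -4.84 and -4.80, with the same doubt over Marchf7, of which another bright probe went up by 1.58. Gjd3, Arg2, Oaz3, Ebf1, Atp9b and Acbd4 rose by 4.44, 4.04, 3.86, 3.82, 3.34 and 3.16. In the lists, the mitosis genes Mos, Kif23, Prc1 and Cdc20 had changes of -4.43, -1.91, -3.81 and -3.41, and Cnot11 and Gdf9 had -2.18 and -0.91, while the sperm list's Oaz3 and Plcz1, the latter by 1.05, the translation factor Eif2b3, by 2.40, and Arg2 rose. These calls are over all genes. Adjusted over the list alone there were 4 sperm genes higher, 1 mitosis gene higher and 4 lower, 1 oocyte gene higher and 2 lower, 2 immediate early genes higher and 1 lower, and 1 chaperone gene in each direction. By that count 2 genes of the unfolded protein response, 1 sterol gene and 1 decay gene were lower, and 1 translation factor and 1 2-cell-stage gene were higher. The 175 calls became 50, 30 and 31 without 0 h replicates a, c and d, with 14, 5 and 5 higher against 36, 25 and 26 lower. They became 99 (27 higher) among the upper 60% of genes, 27 with only these groups in the fit and 594 with array weights.

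At 6 h, 24 genes were lower and 9 higher. Nfkbiz, a regulator of NF-kappaB, fell from 13.24 ± 0.53 to 8.19 ± 0.65, a log2 change of -5.05 (SE 0.78, adjusted p = 0.0115). Cldn4, a tight junction claudin, fell by 4.18, and Hus1, of the DNA damage checkpoint, Rnf130, Tada2a and Il1rap had changes of -4.10, -3.96, -3.77 and -3.75. Gjd3 rose by 5.06, Zbtb7a by 3.00, Fcnb by 1.68, Rexo5 by 1.34, Bag6 by 1.30 and 1700016C15Rik by 1.27. Other probes above background rose by 0.19 for Zbtb7a and by 0.15, 1.88 and 0.81 for Bag6. Of these calls, Hus1, Zbtb7a, Tada2a and Il1rap were lost in 21, 19, 18 and 15 of 35 alternative settings, and 1700016C15Rik and Fcnb in 24 and 17 of 34. This count of 33 was the least stable of those against 0 h: it was 1 without 6 h replicate a, 2 without the 4 dim arrays (chosen after seeing the data), with 0 genes in common, and 0 with only these groups in the fit, against 205 with array weights. It also moved to 11, 15 and 7 without 0 h replicates a, c and d, and to 7 (2 higher, 5 lower) with a replicate block. Higher genes were the majority without each of the 6 h replicates a (1 against 0), b (9 against 7) and d (12 against 10).

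At 2 h and 4 h few genes passed the threshold against the oocytes. By limma, 1857 and 1808 genes had an unadjusted p under 0.05 at these times, against 2644 at 12 h. The small counts therefore do not show that few genes differed. At 2 h, 13 genes were lower and 8 higher: Ext2, an enzyme of heparan sulfate synthesis, had a log2 change of -3.66 (SE 0.55, adjusted p = 0.00915), and Gna14, Eogt, Pusl1, Zfyve16 and Henmt1 had changes of -4.25, -3.62, -3.40, -3.31 and -2.80. Gjd3 rose from 8.74 ± 0.24 to 13.97 ± 1.47, a change of 5.23 (SE 0.93, adjusted p = 0.0215). It was higher in all 21 embryos of the course than in any oocyte. The naming rule asked for groups without overlap and named Gjd3 at every time but 4 h. The separation was therefore open only at 4 h. Adsl, Olfr154, Cbx8, 4932435O22Rik and Arpc5l rose by 4.27, 2.47, 2.06, 1.52 and 1.27. At 4 h, 8 genes were lower and 5 higher: Rnf130, Atp2c2, Pusl1, Ext2 and Snx14 had changes of -3.80, -3.79, -3.50, -3.36 and -2.69, and Rbmxl1 fell from 9.06 ± 0.80 to 7.05 ± 0.23. Fjx1 rose by 3.57 (SE 0.51, adjusted p = 0.00487), Crybg2 by 1.17, and the oocyte-expressed Khdc1c, Tcl1b4 and Zbed3 by 0.91, 0.90 and 0.57, calls lost in 5, 8 and 28 of 35 alternative settings. At 2 h the calls of Eogt and Cbx8 were lost in 24 of 35 and 15 of 34. The majority of lower genes turned without 2 h replicates a, b and d (44, 9 and 16 higher against 20, 4 and 8 lower), without 4 h replicates c and d (6 and 14 higher against 5 and 12 lower) and with array weights (24 higher at 2 h and 80 at 4 h, against 22 and 75 lower). The 21 calls at 2 h became 64 and 13 without 2 h replicates a and b, 11 among the upper 60% of genes and 46 with array weights. The 13 at 4 h became 20 without 0 h replicate c, 26 without 4 h replicate d, 24 with the mean of all probes and 155 with array weights; both were 0 with only the groups compared in the fit.

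**Figure D3:**
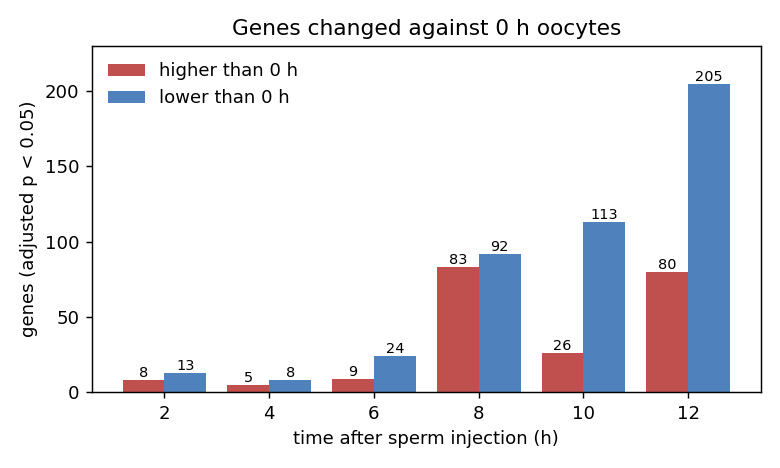
Number of genes (vertical axis) higher (red) and lower (blue) than in the 0 h oocytes at an adjusted p under 0.05, by hours after sperm injection (horizontal axis). Lower genes go from 13 at 2 h to 205 at 12 h, and higher genes from 8 to 80, with 83 at 8 h.

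Against the same oocytes, 13 of the 21 genes called at 2 h, 71 of the 175 at 8 h and 92 of the 139 at 10 h were also called at 12 h in the same direction, and 0 in the opposite one. Across genes the log2 changes at 10 h and 12 h correlated at r = 0.68, against 0.30 in simulated groups with no change and the same shared oocytes, and had a covariance of 0.49 against 0.08. The 3 shared oocytes cannot be split into parts of at least 2, and part of the excess may come from them.

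Between consecutive times the counts were small. From 2 h to 4 h Fjx1 and Crybg2 rose by 3.45 and 1.36, and Adsl and Olfr154 fell by 4.39 and 2.35. From 4 h to 6 h Wdr49, Rexo5 and Vmn1r234 rose by 1.27, 1.17 and 0.89, and Fjx1 and Crybg2 fell back by 3.55 and 1.27. From 6 h to 8 h only Tmigd1 passed, rising by 1.82. From 8 h to 10 h 22 genes were lower and 1 higher: Ebf1, Oaz3 and Atp9b, raised at 8 h, had changes of -3.80, -3.70 and -3.56, and Trappc1 rose by 4.04. From 10 h to 12 h 4 genes were higher and 3 lower: Fkbp7, Gm5662 and Otos rose by 3.00, 2.92 and 2.37 (SE 0.51, 0.50 and 0.37), and so did Olfr715, by 1.94, named after its values were seen, while Acbd7, Pdx1 and Lsm14b fell by 4.42, 1.85 and 0.72. Ribosomal protein genes had a median change of 0.51 from 10 h to 12 h, with 0 called over all genes and 2 higher when adjusted over the list alone (camera adjusted p = 0.0847; adjusted p = 0.267 with an estimated correlation). Of the named calls, Vmn1r234, Rexo5, Olfr154 and Tmigd1 were lost in 28, 27, 24 and 16 of 34 alternative settings, and Trappc1, Atp9b, Oaz3 and Pdx1 in 22, 17, 16 and 15 of 35. All 5 of these counts were 0 with only the groups compared in the fit, and each moved by more than 1.5 times in at least 5 of the 24 settings without 1 array.

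Over all 7 times, 236 genes changed by the F-test. Within the 21 embryos alone, without the oocytes, the fitted linear slope from 2 h to 12 h was negative in 85 genes and positive in 30 past the threshold; whether a course was steady was not tested. The fitted fall of Atf6b was by 0.49 log2 units per hour (SE 0.05, adjusted p = 2.14e-05), that of Tm9sf3 by 0.49 (SE 0.08) and that of Mos by 0.48 (SE 0.07). The steepest fitted rises were those of 0610009B22Rik at 0.47 (SE 0.10), Ttc30b at 0.44 (SE 0.10) and Snhg5 at 0.42 (SE 0.09) log2 units per hour; the mean of Snhg5 went from 8.32 at 2 h to 7.23 at 6 h before it rose, and the slope call of Ttc30b was lost in 20 of 34 alternative settings. Of the 205 genes lower at 12 h, 65 also had a called negative slope among the embryos, and 9 of the 80 higher genes a called positive slope. The 12 h embryos enter both the slope and the choice of these genes, so this overlap is partly built in. The count of 115 stayed between 93 and 133 when any 1 array was left out, and the F-test count of 236 became 107, 109 and 95 without 0 h replicates a, c and d.

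No list of markers of other cells that such a sample could carry passed camera at any time against 0 h. At 12 h none of 28 sperm genes, 30 cumulus and granulosa genes and 19 blood genes was called over all genes or when adjusted over the list alone, and their median changes were 0.27, 0.21 and 0.13 (camera adjusted p = 0.358, 0.358 and 0.791). Of the sperm genes, 2 were higher at 8 h and 1 at 10 h over all genes. Adjusted over the list alone, 1, 2, 0, 4 and 3 were higher at 2, 4, 6, 8 and 10 h, and 0 were lower. The cumulus and blood lists had 0 calls by either count at these times. With fry, the sperm list passed at 4 h (adjusted p = 0.0342). Tnp1, a sperm chromatin protein, was at 7.32 ± 0.07 and 8.56 ± 1.40, Ptx3, of cumulus cells, at 7.74 ± 0.12 and 8.94 ± 1.06, and Cd74, of immune cells, at 6.59 ± 0.06 and 7.28 ± 0.80. Of the remaining genes fixed beforehand, Hspa1b, a heat shock gene, was at 9.24 ± 1.45 and 11.29 ± 0.94 (adjusted p = 0.441), with another probe that changed by -0.30. Pou5f1 was at 14.91 ± 0.11 and 14.86 ± 0.16, Actb at 9.40 ± 0.47 and 9.99 ± 1.13, and Gapdh at 13.07 ± 0.48 and 13.46 ± 0.41, with adjusted p of 0.945, 0.85 and 0.713.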

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

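Of the tests weighed here, those of separate handling of the oocytes, of normalization and of the bright marker probes were chosen only after the result was seen.

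The 205 genes lower at 12 h than in the oocytes, with a median fall of 2.98 log2 units, are the pattern most open to follow-up. The brightness gap between the 0 h and 12 h arrays, combined with the effect of brightness on these genes within embryo times, predicts a shift of only 0.0399 (bootstrap range over genes -0.02 to 0.09). This argues against array brightness as the cause of the fall but does not exclude it. The range leaves out the spread between arrays. The oocyte arrays had finer spacings than every embryo array, so the prediction reaches beyond the arrays it was fitted on. From the 2 h and 4 h to the 8 h and 10 h embryos the same genes changed by a median of -0.882. The bootstrap range was -1.11 to -0.73. These embryos lie outside the comparison that chose the genes but share its estimate of the spread. The median over all genes was 0.03, and 184 of the 205 genes went down. This argues against a shift of the oocyte arrays alone as the cause of the whole fall. The genes share the same arrays, so their number does not measure the spread between arrays. With arrays only centred on their medians the median change was -3.04, but the deposited columns already had a common distribution, with medians over all probes of 7.37 to 7.41, so centring cannot undo that step. The part that normalization plays therefore cannot be told apart from a loss of maternal mRNA after sperm injection, which stays a hypothesis, and a technical difference that grows with time was not tested. The values cover only mRNA captured on oligo-dT beads, so a fall in capture without a loss of mRNA was not tested either.

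The 21 genes that differed between oocytes and 2 h embryos showed another course. Brightness predicts a shift of -0.038 in the direction of the change (bootstrap range over genes -0.133 to -0.00457), against an observed median of 2.08, which argues against it with the same limits. From the 2 h and 4 h to the 8 h and 10 h embryos these genes moved by a median of -0.059 in the direction of the first change (bootstrap range -0.28 to 0.05), with 9 of 21 moving on. This median covers different courses. Adsl was at 6.91, 11.18 and 6.79 at 0, 2 and 4 h. It was at 8.72, 8.28, 6.82 and 8.61 at 6, 8, 10 and 12 h. Gna14 was at 12.05, 7.80 and 12.36 at 0, 2 and 8 h, and at 10.85 and 11.64 at 10 and 12 h. Neither kept its 2 h step in full. Ext2 and Pusl1, at 7.41 and 7.38 at 2 h, were still at 7.69 and 7.95 at 12 h. For genes that kept their step, separate handling of the oocytes and an early response to injection both predict it. The 2 cannot be told apart, since no label gives a batch and the oocytes form 1 group.

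Single probes of Prm1, Gapdhs, Amh and Hbb-bt, genes of sperm, granulosa and red blood cells, were bright in the oocytes, at 11.36, 11.79, 12.45 and 13.26. The other 73 markers of those lists had a median of 7.15 there, against a background of 6.78, with 15 more than 1 unit above it. The brightest of these was Odf2 of the sperm list, at 12.53 ± 0.17, and whether its signal comes from sperm was not tested. Among abundant partners of the bright genes, Tnp2 was at 9.33 ± 0.16, Prm2 at 8.24 ± 0.13, Hba-a1 at 8.75 ± 1.97 and Hba-a2 at 7.91 ± 1.33, while Tnp1, Ptx3 and Inha were at 7.32, 7.74 and 7.57. RNA carried over from such cells is therefore neither excluded nor shown. For sperm RNA, the 0 h oocytes are not labelled as injected with sperm. The 6 other probes of Prm1, Gapdhs and Hbb-bt had a median of 6.93, and Amh has no other probe. The brightest probe stood for each gene, and of 2177 other genes at least as bright and with several probes 473 (21.7%) had other probes within 1 unit of background, so a signal specific to the probe and carried-over RNA cannot be told apart. The rises of Prm1 and Gapdhs at 10 h are open to the same doubt, and no biological explanation was tested.

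Whether chance could give the counts was tested by refitting other splits of the same cells. The real split was the only 1 of 35 to reach its count at 4 h (13, highest other 7), 10 h (139, highest other 6) and 12 h (285, highest other 61) against 0 h. The same held from 8 h to 10 h (23, highest other 10) and from 10 h to 12 h (7, highest other 2). A share of 1 in 35 is the smallest that these splits can give, and it was not corrected over the 11 comparisons. It argues against chance in these 5 comparisons without excluding it. For the F-test and the linear trend, 1 of 100 relabellings, the real one, reached 236 (highest other 6) and 115 (highest other 1), which argues against chance as well. Chance remains an explanation from 2 h to 4 h, where 8 of 35 splits gave at least 4 genes (highest other 10), and from 4 h to 6 h, where 2 of 35 gave at least 5 (highest other 14). With 3 cells against 3, the 10 splits are too few: the counts at 2 h, 6 h and 8 h against 0 h were 21, 33 and 175 in 1 split each, with the highest others at 3, 1 and 2, and from 6 h to 8 h 6 splits gave at least the 1 gene seen (highest other 6).

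Probes outside the gene-level comparisons also changed. Of 8510 probes with no or several gene symbols, 33 changed at 12 h against 0 h by limma, 23 higher and 10 lower. Probe A_52_P552401 rose by 5.04 (adjusted p = 4.24e-06) and A_52_P184028 by 5.08 (adjusted p = 0.000212).

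In 46 of 513 tested groups of 4 cells of 171 named genes, 1 cell stood far from the other 3 by Dixon's test; chance gives about 1 in 20. At 4 h these were replicate a for Gm7969 (9.82), Dppa3 (13.91) and Uqcr10 (11.40), replicate b for 1700016C15Rik (6.49), Nfkbiz (7.61), Vwa2 (9.31) and Pim1 (12.07), replicate c for Hsf2 (10.09), and replicate d for Rnf130 (9.90), Gadd45b (8.97), Nanog (8.09), Rpl9 (7.77) and Rpl17 (10.68). At 10 h they were replicate a for Dipk1b (8.56) and Has3 (8.45), replicate b for Adsl (7.22), Fjx1 (8.13), Med11 (8.77), Snhg5 (11.52), Atf6b (7.95), Rnf215 (11.77) and Ppp1r15a (11.38), replicate c for Tmed9 (8.45), Dcun1d2 (6.91), Ttc30b (11.72) and Bub1b (9.86), and replicate d for Pusl1 (9.89), Henmt1 (8.16), Acbd4 (7.35), Eif1a (7.41) and Gtf2f2 (12.32). At 12 h they were replicate a for C1qtnf12 (9.32), Med11 (10.38), Tmed9 (6.88), Cdk1 (11.12), Lsm5 (9.66) and Cdkn1a (9.28), replicate b for Actb (8.31) and U2af1 (11.96), replicate c for Arpc5l (14.61), Vwa2 (12.39), Slc39a9 (10.98) and Taf6 (10.97), and replicate d for Ebf1 (7.07), Lsm14b (14.16) and Xpc (9.80), all in log2 intensity.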

How the results depend on the processing

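Testing the deposited scores and leaving out the 4 dim arrays were chosen only after the results were seen; the pseudocount alternative was not run, since no pseudocount was used. Of the 119 named calls, 19 were kept in all settings, 51 were lost in 1 to 5 settings and 49 in more (7 of 12 at 2 h, 2 of 11 at 4 h, 10 of 12 at 6 h, 3 of 12 at 8 h, 5 of 12 at 10 h and 7 of 34 at 12 h against 0 h). None reversed, but this says little about direction. Most were named among genes whose groups did not overlap, so leaving out cells cannot turn them. Several other settings leave the group means as they are. Mos, Plat, Bub1b, Atf6b, Ern1, Gdf9, Insig1, Smc3, Tm9sf3, Tmed9, Klhl18, Has3, Slco1a5, Arg2 and Gm7969 kept their 12 h call throughout. Changes near the background of 6.78 are compressed, which limits what dim genes can show. The cause of the lost calls and of the moves below was not tested.

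Each vs 0 h, array weights gave 46 genes at 2 h, 155 at 4 h, 205 at 6 h, 594 at 8 h, 902 at 10 h and 976 at 12 h, all 285 of the 12 h calls included, and 606 for the F-test; they gave 2 from 2 h to 4 h, 6 from 6 h to 8 h and 16 from 10 h to 12 h. With only the groups compared in the fit (fewer cells for the spread), counts were 0 at 2 h, 4 h and 6 h, 27 at 8 h and 162 at 12 h, and 0 in all 5 consecutive comparisons. In the upper 60% of genes they were 11 at 2 h and 99 at 8 h against 0 h, then 2, 1, 0, 0 and 14 over the consecutive intervals, and 178 for the trend. Without the mean-variance trend, 8 h to 10 h gave 12 and 10 h to 12 h 13. Median centring gave 7 (5 lower, 71.4% against 50%), 3 (66.7% lower against 40%) and 14 (64.3% against 42.9%) for 2 h to 4 h, 4 h to 6 h and 10 h to 12 h; quantile normalization again gave 3 (66.7% lower) for 4 h to 6 h and 4 for 6 h to 8 h. The mean of all probes gave 24 at 4 h against 0 h, 5 from 6 h to 8 h and 14 from 10 h to 12 h. The deposited scores gave 20 at 6 h against 0 h, 3 from 4 h to 6 h and 2 from 6 h to 8 h, and shared 20 of 21, 11 of 13, 20 of 33, 143 of 175, 103 of 139 and 254 of 285 calls from 2 h to 12 h. Without the 4 dim arrays counts were 2 at 6 h and 85 at 10 h against 0 h, 8 from 2 h to 4 h, 10 from 6 h to 8 h and 3 from 10 h to 12 h; of the calls against 0 h, 13 of 21 at 2 h, 6 of 13 at 4 h, 0 of 33 at 6 h, 67 of 175 at 8 h, 66 of 139 at 10 h and 244 of 285 at 12 h were shared. Robust eBayes and the minimum change moved no count by over 1.5 times. For lists, 0 tests passed with camera at either correlation, 5 with fry (2-cell-stage, ribosomal and unfolded protein response at 12 h, ribosomal from 10 h to 12 h, sperm at 4 h) and 1 with a replicate block (DNA replication lower at 6 h, adjusted p = 0.0289).

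No label says that the replicate letters pair cells. Deviations of same-letter cells correlated at -0.13 to 0.18 over 62 pairs, over 0.1 in 6, with a mean of 0.0206 against -0.00685 for different letters, and 10 of 24 arrays correlated best with their own letter, against 6.05 by chance; whether letters share a day stays open. The replicate block gave 7 genes at 6 h against 0 h and 2, 3, 6, 11 and 3 over the consecutive intervals, and moved no other count by over 1.5 times.

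Leaving out 1 array gave ranges of 13 to 64 (2 h), 11 to 26 (4 h), 1 to 41 (6 h), 30 to 192 (8 h), 24 to 146 (10 h) and 104 to 311 (12 h) against 0 h, 2 to 37, 2 to 29, 0 to 50, 6 to 61 and 0 to 23 over the consecutive intervals, 95 to 285 for the F-test and 93 to 133 for the trend. Against 0 h, moves over 1.5 times came at 2 h without 2h a (64) and 2h b (13), at 4 h without 0h c (20) and 4h d (26), and at 8 h and 12 h without each oocyte a, c and d (50, 30, 31 and 104, 131, 128), as in the F-test (107, 109, 95). At 10 h they came without 0h a (41), 0h c (52), 0h d (24), 10h a (67), 10h b (73) and 10h c (83), and at 6 h without 0h a (11), 0h c (15), 0h d (7), 2h b (18), 6h a (1), 6h b (16), 8h d (21), 10h b (16), 10h d (18), 12h b (19), 12h c (18) and 12h d (15). From 2 h to 4 h they came without 0h a, 0h d and 10h a (2 each), 2h a (37), 2h b (15), 2h d (28), 4h c and 4h d (17 each). From 4 h to 6 h it was 4h d (13), 6h a (2), 6h d (29) and 0h a, c, d, 2h b, 4h a, 8h c, d, 10h b, d, 12h b, c (3 each). From 6 h to 8 h it was 2h d (7), 6h a (7), 6h b (2), 8h a (14), 8h c (50), 8h d (38), 12h b (3), and 2h a, b, 4h a, b, d, 10h a, b, c, d, 12h a, c, d (0 each). From 8 h to 10 h it was 0h a (7), 0h c and d (6), 4h a (13), 4h d (8), 6h d (6), 8h a (39), 8h c and d (61), 10h a (6), b (10), c (7), d (9), 12h a and c (6) and 12h d (13), and from 10 h to 12 h 6h d (3), 10h a (0), 12h a (23), 12h b (17) and 12h d (18).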

Other observations

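The test of membrane protein families reported here was chosen only after the result was seen. The remaining lists held few or no called genes at 12 h against 0 h. Of 67 chromatin genes 0 passed over all genes or when adjusted over the list alone; Dnmt1, the maintenance DNA methyltransferase, was at 13.89 ± 0.51 in oocytes and 11.60 ± 1.21 at 12 h, and Hdac3 at 10.51 ± 2.48 and 7.30 ± 0.37 (camera adjusted p = 0.22 for the list). Of 56 DNA replication genes 0 passed by either count (camera adjusted p = 0.358), with Lig1, DNA ligase 1, at 11.25 ± 0.46 and 12.82 ± 0.54 and Pola1 at 10.54 ± 0.72 and 8.00 ± 1.01. Of 34 chaperone genes 0 passed over all genes, and 1 rose and 1 fell when adjusted over the list alone, Cct2 and Hspa8, for both of which another probe went the other way (camera adjusted p = 0.472). General transcription (63 genes), splicing (58), the proteasome (37), translation factors (46), ribosome biogenesis (65), pluripotency (21) and p53 targets (21) had 0 calls by either count, with camera adjusted p of 0.652, 0.448, 0.672, 0.96, 0.328, 0.635 and 0.855. In that order their median changes were -0.01, -0.17, 0.11, 0.16, -0.19, -0.03 and 0.01; the mean of the proteasome list was -0.03 and that of the p53 targets -0.14, and camera pointed down for both, against the sign of their medians. Psme3, a proteasome activator, was at 15.58 ± 0.14 and 15.19 ± 0.25, Sall4 at 14.28 ± 0.12 and 13.25 ± 0.63, Utp20 at 10.53 ± 0.51 and 7.31 ± 0.50, and Mdm2 at 13.46 ± 0.11 and 11.84 ± 1.98.

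The genes called at 12 h followed different courses before it. The 205 lower genes had median log2 changes against 0 h of -0.97, -1.18, -1.64, -2.08, -2.29 and -2.98 at 2, 4, 6, 8, 10 and 12 h. The 80 higher genes had medians of 0.46, 0.57, 0.77, 1.02, 0.91 and 2.18. Both sets were chosen on the 0 h and 12 h cells, which inflates the last value and, through the shared oocytes, the others.

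A hypothesis came from the names of the genes that fell: mRNAs of membrane protein families may fall more than others. A set of 589 genes with symbols of the Slc, Tmem, Tspan and Tm9sf families was taken, and the test did not bear the hypothesis out. Only 1 member was called higher, so the set did not hold both Slco1a5 and Slco1a1, which each rose past the threshold. The median change of the set at 12 h was 0.07, at the 9.19th percentile of 10000 lists matched on mean level, and camera gave p = 0.198 (p = 0.101 with an estimated correlation). Among genes over 2 log2 units above background in the oocytes, 18 of 219 members fell (8.22%) against 172 of 7380 others (2.33%; Fisher's exact test, two-sided, p = 8.26e-06), a second look made on the genes that prompted the idea, so it is no independent evidence.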
